A study of Mus musculus with 2 samples.

How the data were processed

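Single-cell RNA was measured in islet cells of mice, with 1 droplet library from a saline group and 1 from a group given CDS. The deposited matrices hold raw UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 7.1, Seurat 4 and edgeR without a version, and genome build mm10; the file header gives Cell Ranger 7.1.0. What Seurat and edgeR were used for, the gene annotation and whether intron reads were counted are not given in the sources used here. The protocol text names both the 3' v3.1 and the v2 chemistry, so the chemistry is uncertain. Per the labels, collagenase was injected through the pancreatic duct and intact islets were picked under a stereomicroscope; no cell sort is stated. The cell type label reads islet b cell, but beta-like, alpha-like, delta-like and PP-like cells were found in both libraries, so cells were assigned here from their own RNA.

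Filters, marker genes, gene lists, the measures compared and most alternatives were fixed before the data were examined; most tests of explanations were chosen after. Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from mitochondrially encoded genes were kept. Doublets were called in each library with Scrublet as in Scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes and its automatic threshold. Kept cells of both libraries were log-normalised and clustered together without integration, with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Each of the 28 clusters was named from fixed markers of cell types, and clusters without a clear best match were left unnamed. The lymphoid share counts every cluster whose best score was a lymphoid class, named or not. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Gene positions and spans came from the GENCODE annotation of mm10, which matched 32235 of the 32285 gene IDs.

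Shares of cells are given with exact Clopper-Pearson 95% intervals. For each class with at least 100 cells in each library, UMIs were summed per library and scaled to CPM (UMIs of a gene over all UMIs of the class, times a constant) with TMM factors (edgeR 4.0.16). The ratio CDS over saline carries the exact conditional 95% interval of a pair of Poisson counts. Levels carry exact Poisson intervals. With 1 library per group these intervals cover counting error only, cells are not replicates, and no p-values were computed. A gene at 0 in a library gets a bound on its ratio, computed against a floor of 3 counts in that library's class sum. Because a few cells can hold most UMIs of a gene, the smallest number of cells that hold 50% of its UMIs was counted in the library where the gene was higher.

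There were 30 fixed gene lists. A list member was measured in a class with at least 50 UMIs over both libraries and a count above 0 in each. It was counted as higher at a ratio of 1.25 or more and as lower at 0.8 or less, with an interval that excluded 1. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on expression, and called apart outside the 2.5 to 97.5 percentiles. Lists with fewer than 5 measured members got no percentile. Gene length (the annotated span of the gene) was added as a further matching variable after seeing the data, together with a ratio adjusted by its running median over gene length. Members counted as higher or lower after that adjustment passed the same ratio limits, with no condition on the interval, so these counts follow a looser rule. Ins2, whose span in the annotation is far longer than its messenger RNA, and the mitochondrially encoded genes get no length-adjusted reading.

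Named genes followed a rule. In beta-like cells these were Adra2a, Ins1, Ins2, Iapp, and the 10 highest and 10 lowest ratios among genes with at least 20 CPM in 1 library and 100 UMIs over both. Mitochondrially encoded, ribosomal protein and listed sex-linked genes, markers of other classes, and genes whose level was under 10% of that in another class were left out. From each list, up to 2 members with the largest absolute log2 ratio at 20 CPM or more were named, in beta-like cells only. In other classes the rule took the 5 highest and 5 lowest at 50 CPM or more, and Gcg, Sst and Ppy in their own classes. PP-like cells were too few for sums of all genes, so Ppy alone is given there. Genes named outside the rule are said to be so.

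Alternatives covered looser filters (200 genes, 500 UMIs, 25% mitochondrial) and stricter ones (1000 genes, 2000 UMIs, 10%), doublets kept, each library clustered alone, Leiden resolutions 0.5 and 2, plain CPM, median-of-ratios factors (DESeq2 1.42.0), CPM without hormone, acinar and mitochondrially encoded genes, a mean over cells, cells thinned to 1 depth, other expression limits, and other denominators for shares. Added after seeing the data were the length adjustment, shares without lymphoid cells, and alpha-like and delta-like cells without their low-depth clusters. Reporting the adrenergic list in classes other than beta-like cells was also decided after seeing the data.

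The methods were tested on simulated data, drawn as Poisson counts from a shared profile with planted changes. That is the model the intervals assume, so their coverage was built in, and uneven levels between cells were not simulated. In a simulated comparison of beta-like cells over 15193 genes, 95.4% of intervals of unchanged genes held a ratio of 1, and planted folds came back as 0.506, 0.688, 1.49 and 2.01. In a simulated macrophage-like comparison over 6878 genes the share was 95.9% and the folds were 0.488, 0.678, 1.52 and 2.03. With a planted length trend, expression matching called apart 20 of 20 random lists of short unchanged genes in beta-like cells (15222 genes) and 18 of 20 in macrophage-like cells (6693 genes). Matching on length as well called 0 of 20 and 3 of 20, so in the macrophage-like simulation length matching left more calls than its nominal rate. The planted trend was shallower than the trends found in these classes, so length matching was not checked on a trend of their size.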

Results

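Islet cells were profiled by droplet single-cell RNA sequencing from DIO mice, as the labels call them, after 2 weeks of saline or of 10 mg/kg of an agent labelled CDS. The series title names a peripherally acting antagonist of the alpha2A-adrenergic receptor, a receptor that lowers cyclic AMP and insulin secretion in beta cells. The labels do not say whether CDS is that compound. Each group had 1 library, so no difference has a replicate check, and the 95% intervals cover counting error only. The saline library held 12453 barcodes and 124343325 UMIs, and the CDS library 7268 barcodes and 141191447 UMIs. Filters kept 11591 saline and 6415 CDS barcodes, and after removal of called doublets 10953 saline cells and 6213 CDS cells remained. Kept cells had a median of 9794 UMIs in the saline library and 19298 in the CDS library. The median mitochondrial share of UMIs was 2.47% and 1.42%.

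The first comparison asked which cells each library held. Lymphoid cells were far more common in the saline library, at 26.1% of kept cells (95% interval 25.3 to 26.9) against 1.03% (0.794 to 1.31) in the CDS library, or 15.7% against 0.993% with the stricter filter. B-like cells numbered 1189 and 35, T-like cells 1139 and 8, and plasma-like cells 93 and 3; the rest of the lymphoid cells are a cluster of 436 and 18 cells that scored best as lymphoid but was not named. Beta-like cells, which make insulin, were 43.0% (42.1 to 43.9) of saline cells and 54.6% (53.4 to 55.9) of CDS cells. Among hormone cells alone the order turned, with beta-like cells at 74.3% (73.2 to 75.4) in the saline library and 68.2% (66.9 to 69.5) in the CDS library. Glucagon-making alpha-like cells took a higher share of hormone cells in the CDS library, at 20.2% (19.1 to 21.3) against 14.6% (13.7 to 15.5).

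Somatostatin-making delta-like cells were 8.55% (7.87 to 9.27) of saline and 9.81% (8.99 to 10.7) of CDS hormone cells. PP-like cells, which make pancreatic polypeptide, were 2.57% (2.20 to 2.99) and 1.81% (1.46 to 2.22), and no PP-like cluster formed in the CDS library when each library was clustered alone. Of all kept cells, endothelial-like cells were 3.37% (3.04 to 3.72) and 4.28% (3.79 to 4.81), and macrophage-like cells 1.52% (1.30 to 1.76) and 2.56% (2.18 to 2.98). Acinar-like cells were 1.91% (1.66 to 2.18) and 1.98% (1.65 to 2.36). With the looser filter they were 1.47% and 4.19%, with the stricter one 1.28% and 3.61%, and at Leiden resolution 2 they were 0.667% and 0.917%. When each library was clustered alone the CDS share was 0.789%. Stromal-like cells were 1.02% (0.843 to 1.23) and 0.483% (0.326 to 0.689), and dendritic-like cells 1.01% (0.834 to 1.22) and 0.225% (0.123 to 0.378). Leaving lymphoid cells out of the denominator, chosen after seeing the data, turned the order of beta-like cells, to 58.2% (57.1 to 59.2) and 55.2% (53.9 to 56.4), of endothelial-like cells, to 4.56% (4.11 to 5.03) and 4.33% (3.83 to 4.86), and of acinar-like cells, to 2.58% (2.25 to 2.95) and 2.00% (1.67 to 2.38). These are shares of the cells recovered.

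**Figure D1:**
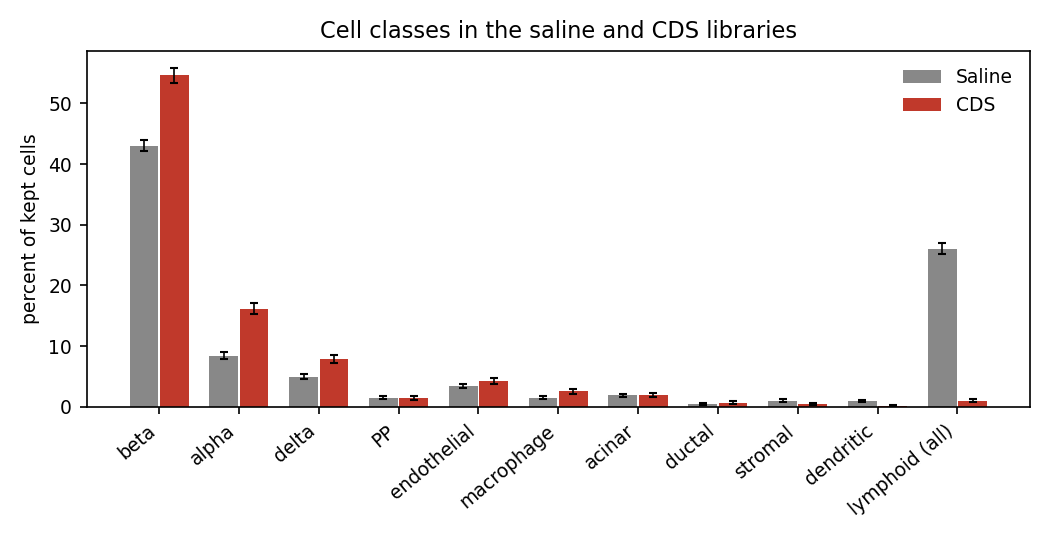
Percent of kept cells in each class, with exact 95% binomial intervals, for the saline (grey) and CDS (red) libraries, 1 library each. Lymphoid cells stand at 26.1% in the saline library and 1.03% in the CDS library.

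The second comparison set beta-like cells of the CDS library (3393 cells) against those of the saline library (4709 cells). Nuclear genes of oxidative phosphorylation were higher in the CDS library almost as a block, with 49 of 52 measured members past the upper ratio limit for list members and 0 past the lower. Glycolysis genes (16 of 19), ribosomal protein genes (30 of 32) and antioxidant genes (15 of 23) were mostly higher as well. Mitochondrially encoded genes were lower (11 of 13), as were 9 of 22 genes of glucose sensing and ion channels, or 2 after an adjustment for gene length. The insulin genes Ins1 and Ins2 stood at ratios of 1.60 and 1.45. Across all genes the ratio followed gene length, with short genes higher and long genes lower in the CDS library.

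Adra2a, the gene of the alpha2A-adrenergic receptor (ENSMUSG00000033717, chromosome 19, 54044151 to 54048982 on mm10), had 2537 saline and 2973 CDS UMIs in beta-like cells. Its TMM-scaled level was 28.6 CPM (27.5 to 29.7) and 34.2 CPM (33.0 to 35.5), a ratio of 1.198 (1.14 to 1.26). The direction turned under plain CPM, with 32.4 and 30.2 CPM, and after adjustment for gene length, at a log2 ratio of -0.15. Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476) had a ratio of 1.60 (1.598 to 1.601), Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) 1.45 (1.453 to 1.455), and Iapp, the gene of islet amyloid polypeptide (ENSMUSG00000041681, chromosome 6, 142298423 to 142303961), 1.72 (1.719 to 1.724). Under plain CPM these were 1.24, 1.13 and 1.34, and Ins1 came to a log2 ratio of 0.038 after the length adjustment.

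Plain CPM lowered the median log2 ratio of all genes by -0.36 in beta-like cells, -0.12 in alpha-like, -0.17 in delta-like, -0.15 in endothelial-like, -0.14 in macrophage-like and -0.11 in acinar-like cells, so ratios are relative to the scaling. Leaving hormone, acinar and mitochondrially encoded genes out of the CPM denominator gave shifts of -0.21 in beta-like and -0.15 in endothelial-like cells. The rank correlation of log2 ratio with gene length was -0.57 over 15197 genes in beta-like cells. It is a correlation across genes, which are not independent replicates. The median log2 ratio was 0.47 in the shortest 20% of genes (median length 3.77 kb) and -0.37 in the longest 20% (130 kb).

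**Figure D2:**
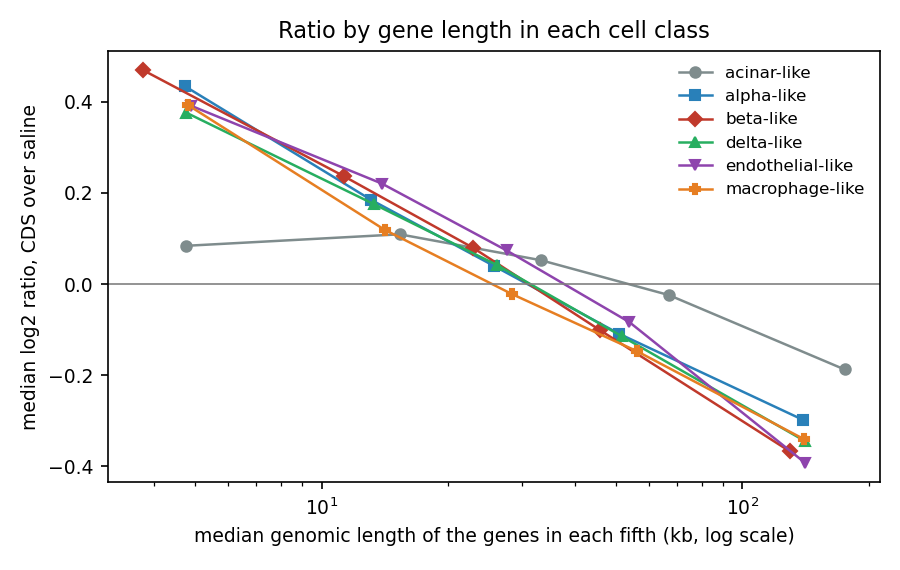
Median log2 ratio CDS over saline (vertical axis) against median genomic gene length in kb (log scale) for bins of 20% of the measured genes, 1 line per cell class. In beta-like cells the medians run from 0.47 in the shortest to -0.37 in the longest genes, and the acinar-like line is the flattest.

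Among the highest single genes in beta-like cells was Gm27168 (ENSMUSG00000099162, a long intergenic RNA on chromosome 8), at 1061 saline and 4957 CDS UMIs and a ratio of 4.77 (4.47 to 5.11). The metallothionein genes Mt1 and Mt3, whose proteins bind metal ions, stood at 3.40 (3.38 to 3.42) and 2.83 (2.62 to 3.07). The cytochrome c oxidase genes Cox7a2 and Cox6c stood at 2.87 (2.81 to 2.93) and 2.83 (2.77 to 2.89). The other genes of the highest 10 were 1810037I17Rik at 3.35, Prelid2 at 2.89, Nop10, a part of the small nucleolar RNPs that modify RNA, at 2.86, Hypk at 2.81 and Smim26 at 2.79. Among these, the length adjustment brought Gm27168, Mt1, Nop10, Mt3 and Smim26 down by over 1.5 times, to log2 ratios of 1.60, 1.13, 0.89, 0.88 and 0.85.

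The lowest gene was the noncoding Gm11867 (ENSMUSG00000087402, chromosome 4), with 2969 saline and 400 CDS UMIs and a ratio of 0.138 (0.124 to 0.153). It was followed by Thsd4 at 0.419 (0.394 to 0.444), the cadherin gene Cdh4 at 0.424 (0.389 to 0.462), B3galt1 at 0.475, Nfatc2, a calcineurin-regulated transcription factor, at 0.477, and the autophagy protease gene Atg4a at 0.478. 5730522E02Rik stood at 0.483, the receptor kinase gene Ror1 at 0.492, and A230057D06Rik and Ptprt at 0.50002 and 0.50004. All 10 are long, from 125 kb for Nfatc2 to 1139 kb for Ptprt. After the length adjustment Gm11867 stood at a log2 ratio of -2.24, Cdh4 at -0.63, Thsd4 at -0.60, B3galt1 at -0.42, 5730522E02Rik at -0.39 and Ptprt at -0.34.

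Nuclear oxidative phosphorylation genes had a median log2 ratio of 1.06, at percentile 100 of random lists matched on expression and also when matched on gene length. Glycolysis genes had a median of 0.75 (percentile 99.96, length-matched 100), with the triose phosphate isomerase gene Tpi1 at a ratio of 2.24 (2.19 to 2.29) and the lactate dehydrogenase gene Ldha at 2.14 (2.01 to 2.29). Antioxidant and thioredoxin genes had a median of 0.58 (99.96, length-matched 98.5), with thioredoxin, Txn1, at 2.53 (2.46 to 2.60) and heme oxygenase, Hmox1, at 2.35 (2.25 to 2.45). Fatty acid oxidation and lipid handling had a median of 0.36 (99.5, length-matched 99.3) with 10 of 21 members higher and 0 lower, but it lay at -0.0040 under plain CPM, with the same percentile, and was not apart with members of at least 20 CPM alone (percentile 94.5). The lipid carrier Fabp5 stood at 2.93 (2.78 to 3.10) and the lipid droplet coat gene Plin2 at 1.77 (1.64 to 1.91).

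Other lists were apart only without length matching. Ribosomal protein genes had a median of 0.87 (percentile 99.98, length-matched 86.4), with Rpl30 at 2.70 and Rps23 at 2.49. Heat shock and dissociation stress genes had a median of 0.77 (99.99, length-matched 92.9), with 14 of 21 members higher and 0 lower. The macrophage activation list, read in beta-like cells, had a median of 0.49 (99.8, length-matched 94.3), with 8 of 14 higher and 2 lower and Lyve1 at 1.502. Glucose sensing and ion channel genes had a median of -0.30 (percentile 0.080), inside the length-matched range at 2.74, with 1 of 22 higher. The calcium channel genes Cacna1c and Cacna1a stood at 0.543 (0.534 to 0.551) and 0.563 (0.551 to 0.575), and Cacna1c at a log2 ratio of -0.23 after the length adjustment.

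Mitochondrially encoded genes had a median of -0.44 (percentile 0.080), with mt-Nd6 and mt-Nd5, subunits of complex I, at 0.472 (0.4445 to 0.5005) and 0.511 (0.505 to 0.517). Nuclear-retained RNAs had a median of -0.61 (0.060, length-matched 0.0), with 5 of 7 lower, Neat1 at 0.583 (0.570 to 0.597) and Kcnq1ot1 at 0.589 (0.574 to 0.605). The exocytosis machinery had a median of -0.21 (0.590, length-matched 1.10), with 4 of 24 higher and 8 lower, or 2 and 2 after the length adjustment (median -0.042). Of its members, Cadps, which primes granules for release, stood at 0.553 (0.543 to 0.563), or a log2 ratio of -0.25 after the length adjustment, and the vesicle fusion gene Vamp8 at 1.68 (1.63 to 1.73). Cholesterol and fatty acid synthesis had a median of -0.18 (0.680, length-matched 0.0), with 2 of 29 higher and 5 lower, the fatty acid synthesis gene Acaca at 0.680 (0.654 to 0.707) and the elongase gene Elovl6 at 0.773 (0.743 to 0.805). That list was not apart when each library was clustered alone (percentile 2.94) or with members of at least 20 CPM alone (3.34).

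Acinar and Reg genes were higher in beta-like cells too, while the alpha, delta and endothelial lists were not apart in the main setting. Acinar digestive enzymes, which beta cells do not make, had a median of 1.18 (percentile 100) with 17 of 18 higher, and the enzyme genes Try4 and Pnlip stood at 4.98 (4.54 to 5.47) and 4.27 (3.86 to 4.73). The Reg family, much of it made by acinar cells, had a median of 1.78 (percentile 100) with 5 of 5 higher. The alpha cell list had a median of 0.036 and turned below 0 under plain CPM, with 6 of 14 higher and 1 lower and glucagon, Gcg, at 1.86 (1.84 to 1.89). At Leiden resolutions 0.5 and 2 the median of that list was 0.44 and 0.44, apart at percentiles 97.82 and 97.83. The delta cell list had a median of 0.23, also below 0 under plain CPM, with 2 of 8 higher and 2 lower and Rbp4 at 2.03 (1.90 to 2.17). The endothelial list had a median of -0.35 (percentile 5.88), with 2 of 14 higher and 7 lower.

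Adrenergic and Gi signalling genes had a median of -0.067 (percentile 9.36), a sign that turned with clustering, with the weighting of cells and with the length adjustment. In that list 3 of 29 members were higher and 8 lower, or 7 higher and 2 lower after the length adjustment (median 0.072), with the Gi-gated potassium channel gene Kcnj6 at 0.557 (0.531 to 0.585) and the adenylyl cyclase gene Adcy9 at 0.566 (0.550 to 0.582). Beta cell identity genes had a median of -0.080 (percentile 10.4, length-matched 0.135), with 3 of 19 higher and 8 lower, and the transcription factor genes Esrrg at 0.573 (0.559 to 0.588) and Myt1 at 0.682 (0.651 to 0.715). Incretin and other secretion receptors had a median of -0.074 (15.2), with 1 of 19 higher and 4 lower, the muscarinic receptor gene Chrm3 at 0.594 and the calcium-sensing receptor gene Casr at 0.651. After the length adjustment Esrrg and Chrm3 stood at log2 ratios of -0.15 and -0.13.

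Positive medians inside the random range all lay below 0 under plain CPM, which shifts all genes alike and leaves the percentiles as they are. These were immediate early and CREB target genes (0.19, 9 of 27 higher and 4 lower, Ier3 2.02, Ier2 1.68), insulin synthesis and granule content (0.065, 6 of 18 and 3, Pcsk1n 1.75, Ptprn2 0.513), and dedifferentiation and disallowed genes (0.070, 5 of 16 and 2). After the length adjustment the medians of the immediate early list (-0.11, 3 higher and 7 lower), dedifferentiation (-0.035), interferon (-0.19), NF-kB (-0.11), cell cycle (-0.17) and delta cell (-0.12) lists were below 0 as well. Serpina7 of the dedifferentiation list had a ratio of 1.08 and turned with the scaling as well. The unfolded protein response (0.21, 10 of 31 and 1), with the translocon gene Sec61b at 2.496 (2.47 to 2.53) and the stress factor gene Ddit3 at 1.77 (1.70 to 1.83), lay at percentile 1.32 with length matching. Interferon response and antigen presentation (0.10, 10 of 28 and 7, Ifi27 2.00, Psmb8 1.88) lay at percentile 0.290 with length matching and at 99.7 with members of at least 20 CPM alone. Inflammation genes of the NF-kB list (0.22, 6 of 16 and 4, Nfkbia 1.90) lay at percentile 98.5 with members of at least 20 CPM alone.

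Lcn2 of that list, an iron-scavenging acute-phase gene, stood at 3.29 (3.20 to 3.38), but 25 of 3393 CDS cells (0.737%) held 50% of its UMIs. Apoptosis, p53 and senescence genes (0.10, 7 of 22 and 2, Cdkn1a 1.98, Bax 1.77), cell cycle genes (0.015, 6 of 21 and 6, H2afz 1.96, Cdk4 1.67) and polyamine and growth signalling genes (0.26, 4 of 12 and 1, Srm 1.49, Ddit4 1.41) complete that set. Ddit4 lay at a log2 ratio of -0.069 after the length adjustment. The sex-linked list had 4 measured members and a median of -0.10, with Uty at 0.677 and Eif2s3y at 1.16, the latter under 1 with plain CPM. The 7 beta-like clusters, formed without integration, were mostly split by library. The largest held 244 saline and 1904 CDS cells, and others 1689 and 220, 1394 and 206, and 842 and 181. Genes such as Mt2, Mt1, Ddit3 and Hmox1 led a cluster of 121 and 640 cells. Lcn2, Fgg and Hamp were among the leading genes of a more evenly shared cluster of 135 and 88. The sums mix these clusters, and whether the split reflects cell states or the libraries was not tested.

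**Figure D3:**
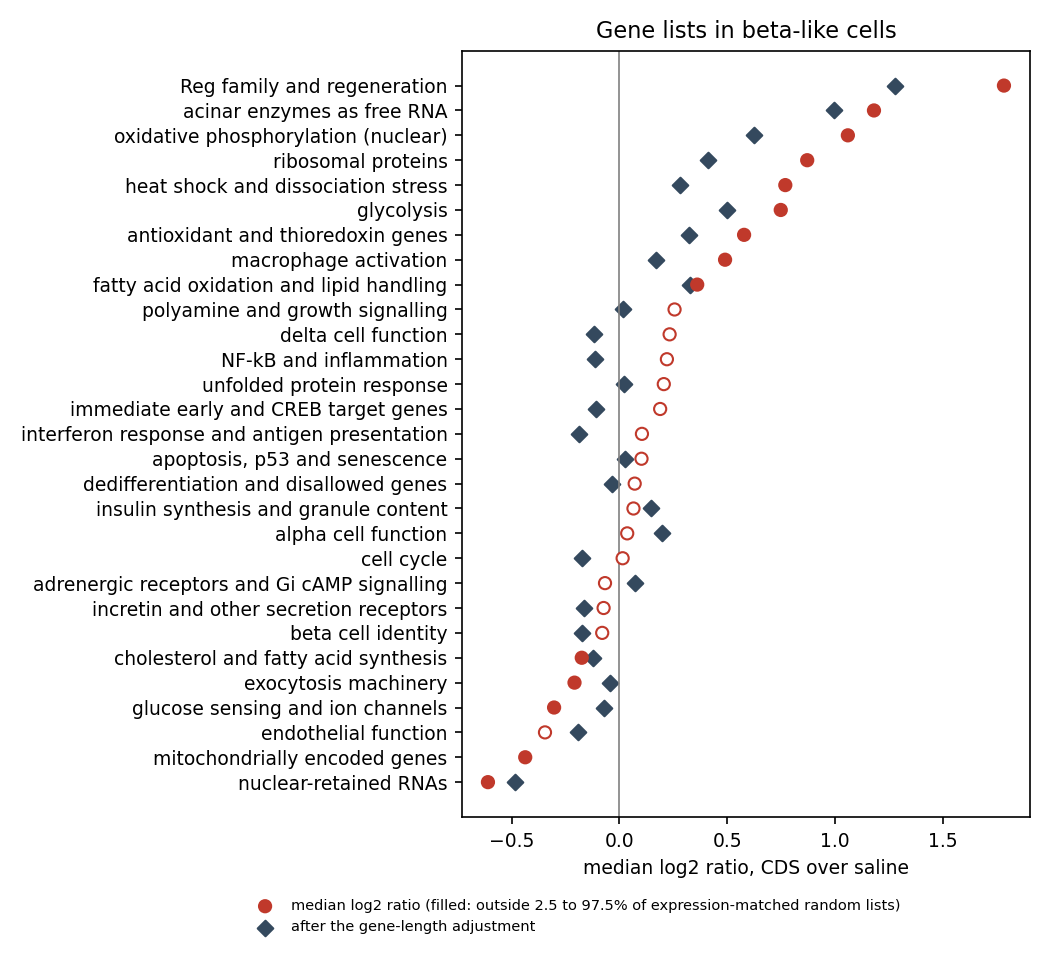
Median log2 ratio CDS over saline of each fixed list in beta-like cells, filled where outside the range of expression-matched random lists, with diamonds after the gene-length adjustment. Oxidative phosphorylation stands at 1.06 and nuclear-retained RNAs at -0.61; under plain CPM the open circles right of 0 and fatty acid oxidation fall below 0.

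The third comparison asked the same of 5 other classes. Nuclear oxidative phosphorylation genes were higher in the CDS library in alpha-like (46 of 52 members), delta-like (40), endothelial-like (42) and macrophage-like (36) cells, with medians of 0.84, 0.77, 0.62 and 0.58. Glycolysis genes were higher with medians of 0.68, 0.57 and 0.87 in alpha-like, delta-like and endothelial-like cells, and at 0.47 in macrophage-like cells, inside the random range at percentile 97.4 but above it with length matching (99.8), the looser filter (97.54), a mean over cells (98.8) and no expression filter (99.6). Mitochondrially encoded genes were lower in the same classes, with medians of -0.44, -0.34, -0.55 and -0.30. Ribosomal protein genes had medians of 0.62, 0.60, 0.56 and 0.65, which with length matching were apart only in macrophage-like cells (percentile 98.0). Rank correlations of ratio with gene length were -0.63 in alpha-like (11936 genes), -0.63 in delta-like (11660), -0.59 in endothelial-like (8788), -0.47 in macrophage-like (6885) and -0.23 in acinar-like cells (6000).

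In alpha-like cells (925 saline and 1005 CDS cells), Gcg stood at 1.29 (1.284 to 1.292), and the alpha cell list had a median of 0.22 (percentile 93.1), with 5 of 14 higher and 1 lower. Inflammation genes of the NF-kB list were higher, with 8 of 14 members higher and 0 lower and a median of 0.77 (percentile 100 with and without length matching). The acute-phase genes Saa3 and Lrg1 stood at 18.6 (12.3 to 29.5; 23 and 624 UMIs) and 8.10 (6.51 to 10.2; 88 and 1042 UMIs). Of 1005 CDS cells, 4 held 50% of the Saa3 UMIs and 23 those of Lrg1. Lcn2, named after its values were seen, stood at 19.9 (17.3 to 23.0; 202 and 5874 UMIs), with 50% of its UMIs in 13 cells. Crybb3, a crystallin gene, stood at 4.05 (3.75 to 4.38), C2cd4b at 2.86 (2.51 to 3.26) and 1810037I17Rik at 2.83 (2.55 to 3.15), while Gm11867 stood at 0.108, Rasgef1b at 0.478, Chrm3 at 0.481, the splicing regulator gene Rbfox1 at 0.486 and Cux2 at 0.506. C2cd4b came to a log2 ratio of 0.89 after the length adjustment. Acinar enzymes had a median of 1.13 (percentile 100) and the interferon list 0.12 (82.1), or -0.14 (2.32) after the length adjustment, 0.27 (97.55) with a mean over cells and 0.64 (99.99) with members of at least 20 CPM alone.

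**Figure D4:**
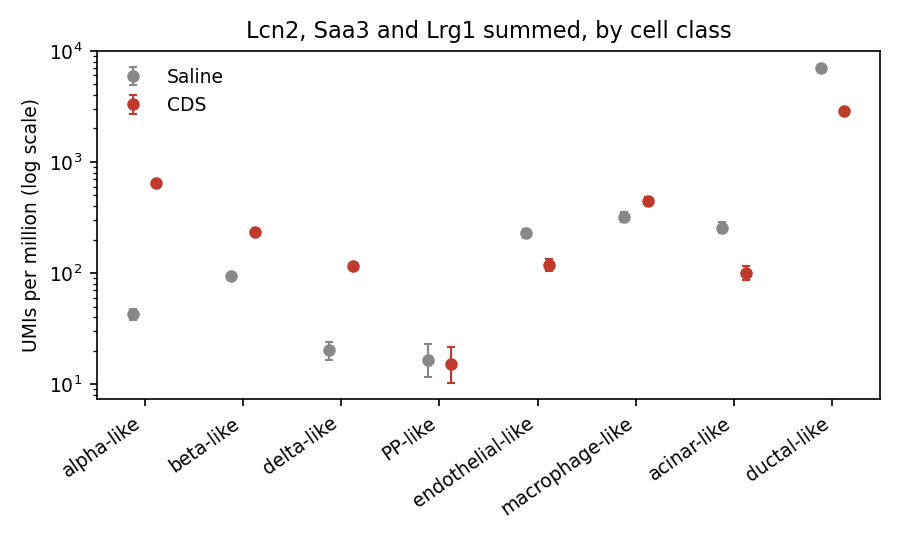
Summed Lcn2, Saa3 and Lrg1 level in plain CPM (log scale) in the classes shown of the saline (grey) and CDS (red) libraries, with exact 95% Poisson intervals, 1 library each. Alpha-like cells stand at 42.7 and 646, and of the classes shown ductal-like cells are highest in both libraries at 7005 and 2896.

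In delta-like cells (542 and 488), the somatostatin gene Sst stood at 0.877 (0.873 to 0.881). Hypk at 2.59, 1810037I17Rik at 2.56, the transcription factor gene Cebpd at 2.52, C2cd4b at 2.44 and Fmc1 at 2.44 were highest. The potassium channel gene Kcnh7 at 0.279 (0.228 to 0.338), Rcan2 at 0.489, Cdh4 at 0.501, Hnf4a at 0.508 and Ror1 at 0.509 were lowest. The delta cell list had a median of -0.073 (percentile 23.8), turning above 0 with the weighting of cells, or -0.16 (0.915) after the length adjustment. Acinar enzymes had a median of 0.76 (percentile 100), the macrophage activation list 0.62 (99.9), the interferon list 0.20 (95.1), and the NF-kB list 0.061 (64.3), which turned below 0 under plain CPM. The interferon list passed the upper limit with a mean over cells (0.31), with thinned cells (0.42) and with members of at least 20 CPM alone (0.44), and the lower one without an expression filter (-0.22). In the 163 saline and 90 CDS PP-like cells, Ppy made up 180809 and 254823 plain CPM (393771 and 505983 UMIs).

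In endothelial-like cells (369 and 266), the hypoxia-induced gene Ankrd37 stood at 3.30 (2.76 to 3.95) and Rassf4 at 3.21 (2.44 to 4.25). Higd1a, a nuclear gene for a mitochondrial protein, stood at 2.83 (2.56 to 3.13). The chemokine gene Cxcl3 stood at 11.1 (6.26 to 21.5), with 1 of 266 cells holding 50% of its UMIs, and the interferon-induced Ifit2 at 2.78 with 2 cells. With a mean over cells, Cxcl3 and Ifit2 came to log2 ratios of 1.98 and 0.85. The lowest genes rested on 2 to 5 of 369 saline cells. Glycam1, a ligand of L-selectin made in lymph node vessels, was at least 53.4-fold lower (193 and 0 UMIs), and Ubd at least 41.8-fold lower (151 and 0). Cyp1b1 stood at 0.00628 (0.000158 to 0.0354; 192 and 1 UMIs), Sema3a at 0.00733 (0.000884 to 0.0267; 329 and 2) and Cd55 at 0.0151 (0.00310 to 0.0447; 239 and 3). The endothelial list had a median of 0.026, below 0 under plain CPM, and was apart on the lower side with a mean over cells (-0.070) and with thinned cells (-0.25). The NF-kB list had a median of -0.20 (percentile 1.29), or percentile 3.52 without an expression filter. The interferon list had a median of -0.15 (0.890), which was not apart with the stricter filter, a mean over cells or members of at least 20 CPM alone. Macrophage activation genes had a median of -0.93 (0.0), or -0.36 (4.89) without an expression filter, the insulin and granule list -0.23 (0.215) and acinar enzymes -0.27 (1.74), the last turning to 0.43 with a mean over cells.

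In macrophage-like cells (166 and 159), the leukotriene synthesis gene Ltc4s stood at 7.72 (3.76 to 18.4), with 50% of its UMIs in 9 of 159 cells. Chil3 was at least 31.3-fold higher (0 and 143 UMIs), with 50% of its UMIs in 1 cell. Stmn1 stood at 5.54 (3 cells), Fam183b at 5.14 (5 cells; a log2 ratio of 1.18 with a mean over cells) and Gm11808 at 3.82 (18 cells). The lowest were the immunoglobulin gene Ighg3, at least 387-fold lower (762 and 0 UMIs, 1 of 166 cells), Serpina3f at 0.00534 (0.000134 to 0.0303; 123 and 1 UMIs, 2 cells), Gm15056 at 0.0116 (3 cells), the carbonic anhydrase gene Car2 at 0.0168 (0.00342 to 0.0504; 117 and 3 UMIs, 1 cell) and Tmem267 at 0.0352 (2 cells). Interferon genes were lower, with 13 of 28 lower and 5 higher and a median of -0.31 (percentile 0.0), which was -0.061 (8.80) with a mean over cells and 0.024 (11.2) with thinned cells. The insulin and granule list was higher at 0.93 (percentile 100) and so were acinar enzymes at 1.09 (100), neither of which macrophages make. The macrophage activation list had a median of 0.24 (81.1), with 9 of 19 higher and 4 lower, and the NF-kB list 0.19 (82.8), or 0.47 (98.5) with thinned cells.

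In acinar-like cells (209 and 123), the Reg genes Reg3a and Reg3d stood at 9.53 (7.84 to 11.7) and 4.58 (3.36 to 6.38), the colipase gene Clps at 4.89 (4.70 to 5.09) and the granule gene Zg16 at 4.24 (3.97 to 4.53), each with 50% of UMIs in 4 or 5 of 123 cells. Slc7a11 stood at 5.10, with 2 cells. Lowest were 1810009J06Rik at 0.00510 (0.00105 to 0.0150; 432 and 3 UMIs), Gm2663 at 0.0317, the protein C receptor gene Procr at 0.125, Ramp1 at 0.150 and Mecom at 0.177, resting on 3 to 8 of 209 cells. Acinar enzymes had a median of 0.54 (percentile 100) but -0.37 with the stricter filter. Oxidative phosphorylation genes had a median of 0.16 (98.3), not apart with length matching (86.4). Glycolysis lay at 0.064, below 0 under plain CPM, mitochondrially encoded genes at -0.091 (11.7), ribosomal protein genes at -0.025 (22.6), NF-kB genes at -0.27 (5.41), and interferon genes at -0.41 (0.36), or 0.0012 with thinned cells. With the stricter filter glycolysis at 0.40 (98.3) and NF-kB genes at -0.56 (0.13) were apart, while interferon genes at -0.062 (26.2) were not. Single-gene folds in this class moved by over 1.5 times with the stricter filter or a mean over cells for most of the named genes, so they give a direction more than a size.

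Adrenergic and Gi signalling genes were lower in delta-like cells, with 10 of 27 lower and 4 higher and a median of -0.27 (percentile 0.175), and in endothelial-like cells, with 6 of 20 lower and 1 higher and a median of -0.17 (2.02). With length matching neither was apart (7.11 and 53.8), and the delta-like median was 0.090 after the length adjustment. In thinned cells neither was apart, at -0.13 and 0.070, nor was the endothelial-like list with members of at least 20 CPM alone (2.77). The medians in alpha-like (-0.14, percentile 6.98), macrophage-like (-0.063, 31.9) and acinar-like cells (0.0034, 49.7, below 0 under plain CPM) were inside the random range. The alpha-like list fell below it with a mean over cells (-0.23), with thinned cells (-0.22) and without an expression filter (-0.18).

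A further comparison placed Adra2a across classes, in plain CPM. Beta-like cells had the highest level, at 32.4 saline and 30.2 CDS. Delta-like cells had 7.78 (5.70 to 10.4; 46 UMIs) and 13.0 (10.7 to 15.6; 110 UMIs), a TMM-scaled ratio of 1.87 (1.31 to 2.70). Ins2, looked at there after seeing the data as a measure of beta cell RNA, was higher in the same delta-like sums at 2.20 (2.19 to 2.21), with 50% of its CDS UMIs in 18 of 488 cells. Acinar-like cells had 14.1 (8.23 to 22.6) and 16.9 (11.4 to 24.2), a ratio of 1.30 (0.693 to 2.51) that turned to a log2 ratio of -0.61 with the looser filter. The acinar-like sums also held much beta cell RNA, with Iapp, chosen after seeing the data, at 20111 and 34501 CPM, so this level cannot be read as acinar expression. Alpha-like cells had 2.86 (1.77 to 4.37) and 2.23 (1.46 to 3.26), endothelial-like cells 4.02 (1.93 to 7.39) and 3.05 (1.22 to 6.28), macrophage-like cells 1.90 (0.231 to 6.88) and 3.96 (1.59 to 8.17), and PP-like cells 2.30 (0.746 to 5.36) and 2.01 (0.549 to 5.16). In these 4 classes no difference was detectable at this depth.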

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

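The tests of cytoplasmic RNA loss and the first ductal test were written before their results were seen; all other tests here were chosen after.

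Lymphoid cells made up 26.1% of the saline cells and 1.03% of the CDS cells, or 15.7% and 0.993% with the stricter filter. A loss of shallow cells from the CDS library is argued against only as far as a fixed UMI cut marks them. Non-lymphoid cells under 3000 UMIs were 6.53% of 8096 saline and 6.54% of 6149 CDS cells, a ratio of 0.9995. Kept cells had medians of 9794 and 19298 UMIs, so this cut need not mark the same kinds of cell in both libraries. Lymph node tissue carried along with the saline islets, which were hand-picked with no stated sort, is a candidate explanation. In stromal-like and endothelial-like cells pooled, 6 lymph node stroma genes (Madcam1, Chst4, Fut7, Tnfsf11, Il7, Bst1) were 7.49 times (4.67 to 12.7, from 195 and 19 UMIs) higher per UMI of the pool in the saline library. Of these genes, 4 also had UMIs in the CDS library and Fut7 had 0 in both. Ccl21a, Ccl19, Cxcl13 and Glycam1, seen beforehand, gave 21.0 (17.3 to 25.7, from 3018 and 105 UMIs). The pool held 112 stromal-like and 369 endothelial-like saline cells, against 30 and 266 CDS cells. This mix alone would make any stromal gene higher in the saline pool, but by less than these ratios, given the counts of cells. The ratios come from 1 library per group and do not by themselves show lymph node tissue. An effect of the treatment on lymphoid cells in or around the islets stays open and was not tested.

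Long genes were lower in the CDS library in 6 classes, and nuclear oxidative phosphorylation genes were higher. Thinning cells to 1 depth left rank correlations of -0.532 or stronger in 5 classes. Thinning keeps each gene's expected share of a cell's UMIs, so it changes mainly how cells are weighted. It argues against the weight of deeper cells as the source there, and cannot decide whether capture differed along with depth. In acinar-like cells the thinned value of -0.0988 rests on 716 genes (-0.156 unthinned), too few to tell. That class was set apart after its value was seen. More cytoplasmic RNA lost from saline cells may underlie the length trend, since cells above the median mitochondrial share differed from those below it with a rank correlation with length of 0.333 in saline and 0.456 in CDS beta-like cells, the only class tested. Nuclear-retained RNAs, which bear on this, had medians of -0.61 in beta-like, -0.41 in alpha-like, -0.35 in delta-like and -0.98 in endothelial-like cells. Their medians were 0.096 (percentile 59.2) in macrophage-like cells, with 5 measured members, and 0.20 (86.6) in acinar-like cells. For oxidative phosphorylation genes, that within-library comparison cannot decide whether the same loss plays a part. Their median log2 ratio, cells below the median mitochondrial share over those above, was 0.0365 in saline and -0.0343 in CDS beta-like cells. These medians lay at length-matched percentiles 19.8 and 37.0, so no rise was seen. The mitochondrial share may also follow the amount of mitochondria in a cell, which could hide a rise of these genes. Gene length is argued against as the whole cause of their difference between libraries by a length-matched percentile of 100. An effect of the treatment on these genes stays open and was not tested, since 1 library per group confounds it with preparation.

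Lcn2, Saa3 and Lrg1 summed to 42.7 (38.1 to 47.7) plain CPM in saline and 646 (632 to 661) in CDS alpha-like cells, against 94.0 and 233 in beta-like 20.1 and 117 in delta-like, 322 and 448 in macrophage-like and 16.5 and 15.1 in PP-like cells, and with the opposite order in endothelial-like (227 and 118), acinar-like (256 and 99.99) and ductal-like cells (7005 and 2896). Free RNA is argued against by a ratio of 42.8 (29.9 to 63.4) to PP-like cells of the same library. That reference was chosen after a first bound left the question open at 1.44 (1.34 to 1.55) times macrophage-like cells, the highest of PP-like, endothelial-like and macrophage-like cells. A few cells held most of the UMIs, as 1.29% of CDS alpha-like cells (13 of 1005) held 50% of those of Lcn2 and 1.30% (12 of 925) did in the saline library, but they are argued against as the whole difference: without the 51 highest CDS cells the rest stood at 161 (154 to 169) plain CPM, 3.78 times (3.35 to 4.28) the level of all saline alpha-like cells. Ductal cells caught with alpha cells were left open by the first test, where the 13 cells carried ductal markers at 17.9% of the ductal level, between bounds of 10% and 20%. They held 3551 (3283 to 3834) plain CPM of the markers, against 1854 (1829 to 1879) in the other 992 CDS alpha-like cells and 19822 in ductal-like cells. The bound of 10% thus lay near the level of the other alpha-like cells, and the first test could hardly fall below it. Over all CDS alpha-like cells the markers reached 1880 (1855 to 1905) plain CPM, 42.5% of the 4422 that ductal RNA would bring, which argues against it as the whole source. Most of that level lay outside the 13 cells. A response of alpha cells to the treatment stays open and was not tested.

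Where the median of a list moved in opposite directions in a pair of classes, the difference was not tested. The insulin and granule list was at a log2 ratio of 0.93 in macrophage-like and -0.23 in endothelial-like cells, 1.16 apart. NF-kB genes were at 0.77 in alpha-like and -0.20 in endothelial-like cells, 0.97 apart. Acinar enzymes were at 1.18 in beta-like and -0.27 in endothelial-like cells, 1.45 apart, though the latter was 0.43 with a mean over cells and 0.028 with thinned cells. Macrophage activation genes were at 0.62 in delta-like and -0.93 in endothelial-like cells, 1.55 apart, though the latter was -0.36 without an expression filter. In cells left unnamed, outside the report's comparisons, erythroid markers came to 880.8 plain CPM in the CDS library (852 to 911; 3487 UMIs) against 14.0 (10.8 to 17.8; 66 UMIs) in the saline library.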

How the results depend on the processing

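The length adjustment, the shares without lymphoid cells and the omission of low-depth clusters were chosen after the results were seen; the other settings were fixed before. Over all settings, 1375 of 1383 gene values kept their direction while 421 moved past the limit set, and of 909 list values 82 turned direction, 844 kept their call, 30 were weaker, 27 stronger and 8 reversed. Most of these genes were named for extreme ratios in the same data, so few could turn direction and that count is no measure of robustness. For lists, plain CPM, median-of-ratios factors and CPM without hormone, acinar and mitochondrially encoded genes shift all genes alike and keep the percentile. Their 78 values each could change a call only by a turned sign, so the count of kept calls is no measure of robustness either. Of 118 share values, 71 stayed within the limits set and 47 moved, and omitting low-depth clusters kept the direction of 24 of 24 gene and 19 of 19 list values. Depth limits which genes are read, since a list member needed at least 50 UMIs, and the cause of each move was not tested. Values are saline and then CDS shares in percent, or median log2 ratios of lists. With the looser filter, shares were beta 40.8 and 50.2, alpha 7.89 and 14.7, delta CDS 6.79, macrophage saline 1.88, acinar 1.47 and 4.19. With the stricter filter they were beta 53.1 and 58.1, alpha saline 9.81, delta saline 5.61, PP 1.76 and 2.09, endothelial saline 3.83, acinar 1.28 and 3.61, lymphoid saline 15.7. With doublets kept they were beta CDS 52.9, delta 4.05 and 6.36, lymphoid saline 24.9. With each library clustered alone they were beta 49.1 and 57.0, alpha CDS 17.4, delta CDS 6.86, PP CDS 0.0 and acinar CDS 0.789. At resolution 2 they were delta 4.28 and 6.57, acinar 0.667 and 0.917. Of hormone cells, beta were 74.3 and 68.2, alpha 14.6 and 20.2, delta 8.55 and 9.81, PP 2.57 and 1.81. Of saline cells without lymphoid cells, beta were 58.2, alpha 11.4, delta 6.69, PP 2.01, endothelial 4.56, macrophage 2.05 and acinar 2.58; of such CDS cells, endothelial were 4.33 and acinar 2.00. Adra2a stood at a log2 ratio of -0.61 in acinar-like cells with the looser filter, and in beta-like cells at -0.10 with plain CPM, 0.054 without hormone, acinar and mitochondrially encoded genes, and -0.15 length-adjusted, where Ddit4 stood at -0.069. For lists with the looser filter, acinar oxidative phosphorylation at 0.11 lost its call and macrophage glycolysis at 0.45 gained one. With the stricter filter, acinar interferon (-0.062) and endothelial interferon (-0.024) lost theirs, acinar glycolysis (0.40) and NF-kB (-0.56) gained one, and acinar enzymes in acinar-like cells reversed (-0.37). Clustered alone, beta cholesterol synthesis (-0.10) lost its call, and at resolutions 0.5 and 2 the alpha list in beta-like cells (0.44 and 0.44) gained one. Under plain CPM, beta fatty acid oxidation reversed (-0.0040). With a mean over cells, interferon gained a call in alpha (0.27) and delta (0.31), as did the alpha adrenergic list (-0.23), the endothelial list in its class (-0.070) and macrophage glycolysis (0.56); interferon lost it in acinar (-0.37), endothelial (-0.028) and macrophage (-0.061), and endothelial acinar enzymes reversed (0.43). In thinned cells, acinar oxidative phosphorylation (0.22), the delta adrenergic list (-0.13), beta Reg genes (1.86) and delta macrophage activation (0.28) lost their calls, the last pair for too few members. There, interferon in acinar (0.0012) and macrophage (0.024) and acinar enzymes (0.028) and the adrenergic list (0.070) in endothelial reversed, while delta interferon (0.42), the alpha adrenergic list (-0.22), the endothelial list (-0.25) and macrophage NF-kB (0.47) gained one. With members of at least 20 CPM alone, interferon in alpha (0.64), beta (0.69) and delta (0.44) and beta NF-kB (0.76) gained calls. Weaker there were beta heat shock (0.60), cholesterol (-0.19), fatty acid oxidation (0.34) and macrophage activation (0.54), endothelial interferon (-0.069) and the endothelial adrenergic list (-0.13), while delta macrophage activation (0.83) had too few members for a call. Without an expression filter, delta interferon (-0.22), the alpha adrenergic list (-0.18) and macrophage glycolysis (0.48) gained calls, and endothelial NF-kB (-0.20), acinar enzymes (-0.20) and macrophage activation (-0.36) lost them. Length-adjusted, calls were lost for ribosomal proteins in alpha (0.18), beta (0.41), delta (0.23) and endothelial (0.12), acinar oxidative phosphorylation (0.087), the endothelial adrenergic list (-0.050), and beta ion channels (-0.072), heat shock (0.28) and macrophage activation (0.17). The delta adrenergic list reversed (0.090). Gained there were alpha interferon (-0.14), beta identity (-0.17), unfolded protein response (0.023) and interferon (-0.19), the delta list in its class (-0.16) and macrophage glycolysis (0.40).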

Other observations

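The genes and adjusted values here were chosen after seeing the data. After the length adjustment, the highest genes of beta-like cells included Prelid2 at a log2 ratio of 1.71, Gm27168 at 1.60, Gm15283 at 1.46, Fam162a at 1.42, the copper chaperone gene Atox1 at 1.28 and Mcub, a subunit of the mitochondrial calcium uniporter, at 1.27. Their unadjusted ratios were 2.89, 4.77, 2.19, 2.72, 2.73 and 2.20. Among nuclear genes that do not mark other classes, the lowest after Gm11867 included the noncoding B830012L14Rik at -1.19, Gm34759 at -1.14 and Gm26917 at -1.11, the immediate early gene Fosb at -0.97 and Ucn3, a hormone of mature beta cells, at -0.82. Fosb had an unadjusted ratio of 0.641 (0.598 to 0.687) and Ucn3 of 0.766 (0.737 to 0.795). The maturity factor gene Mafa stood at 0.946 (0.924 to 0.969) before and at a log2 ratio of -0.59 after the adjustment.

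Smaller classes had too few cells for sums of all genes. Ductal-like cells were 0.466% (0.347 to 0.612; 51 cells) of the saline and 0.708% (0.515 to 0.9496; 44 cells) of the CDS cells. Cells in a cluster led by proliferation genes such as Top2a and Mki67 were 0.502% (0.379 to 0.653; 55 cells) and 0.789% (0.584 to 1.04; 49 cells). Cells left unnamed numbered 1120 and 506, the lymphoid-scoring cluster included.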
